A study of Homo sapiens with 6 samples.

How the data were processed

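Gene expression was measured by paired-end sequencing of mRNA libraries on an Illumina NovaSeq, per the labels' protocols, in 6 libraries of the line labelled B4G12, 3 given a control siRNA and 3 an siRNA against NAMPT. Groups and replicate numbers were taken from the sample titles. The authors supplied whole-number counts per gene and library, per the file headers, with no normalization. The deposited FPKM values, per the file headers, equal the count divided by a gene length and by the library's total count, with the same length in all libraries. The aligner, the counting program, its treatment of strand and of reads with several matches, and the annotation release are not given in the sources used here. The submitters' processing notes name the builds GRCh38 and mm10. Gene IDs in the table are human, 98.5% of them are in GENCODE release 29, and 94.9% of the shared IDs have an identical position there, so coordinates are given as GRCh38. No column of other samples was left over, and the table has 50868 genes, of which 26457 had a count in at least 1 library.

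Total counts were 19510796 to 22364717 per library. A count of 3, the floor used for a gene not seen, corresponds to 0.134 to 0.154 CPM. No 2 libraries held identical values, and replicate pairs differed by more than sampling noise (chi-square per gene of 11.7 to 16.7 where 1 is expected from sampling).

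The counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit and glmQLFTest), two-sided, siNAMPT against siControl with no other term, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the root of the F statistic. CPM are scaled by TMM, whose factors lay between 0.988 and 1.02. For NAMPT an exact two-sided permutation test on log2 CPM was added. A total of 40 gene lists were fixed before the data were examined, 36 of which had at least 5 testable members. They were tested with camera in limma 3.58.1 (inter-gene correlation preset to 0.01, and again estimated) and with fry, which called 32 lists as moving one way on balance but does not compare a list with other genes. Of 1120 list symbols, 1118 were matched to the table.

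The genes named in the text follow a rule fixed at the same time. NAMPT is always named. The rule then takes the 12 largest rises and 12 largest falls among genes with a symbol, adjusted p under 0.05, libraries of the groups not overlapping and a mean FPKM of at least 5 in the higher group. From each list it takes up to 2 risers and 2 fallers past the threshold with the largest changes, and all NAD synthesis genes may be named. Some genes that the rule takes are not reported here. Genes outside it are said to have been chosen after their values were seen, or serve as marker levels or as words' carriers.

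The 3′ UTR of 1 transcript per protein-coding gene was taken from GENCODE 29, and 11498 of 12488 tested coding genes (92.1%) with a UTR of at least 50 bases and a mean of at least 1 CPM were searched for all 7-base words. Residuals were permuted 100 times. In the same scan, words planted with a shift of −0.3 in simulated values came first in 10 of 10 trials. Transcript length and GC content, used for an offset fitted with splines in each library, came from the same annotation and covered 99.5% of genes tested.

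The gene and list tests were tested on simulated data, drawn for siNAMPT against siControl over 15213 genes from the real means, library sizes and dispersions, with 200 genes changed, 50 at each size. The share called was 4% at 1.25-fold, 46% at 1.5-fold, 74% at 2-fold and 96% at 4-fold, 10.6% of the calls were unchanged genes, and 1 gene was called when nothing was changed. In a like simulation camera called a list shifted among unchanged genes and not an unshifted one. Both simulations drew genes independently and changed far fewer genes than were called in the data. They therefore do not cover lists with correlated members.

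Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors (RLE) in edgeR, no filter on low counts, limma on log2(FPKM + 1) for genes with FPKM of at least 1 in at least 3 libraries, the replicate number as a block, and leaving out each library in turn. Alternatives that apply only to a table without counts were not run. With DESeq2 the lists were tested with cameraPR, a form of camera that takes 1 statistic per gene, on the DESeq2 statistics. The preset correlation was the same, but gene statistic and list test differ together. Scans and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.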

Results

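RNA was sequenced from cells labelled B4G12, an immortalised line derived from human corneal endothelium, the cell layer at the back of the cornea that pumps fluid out of the stroma. One group of 3 libraries came from cells given a control siRNA (siControl) and another group of 3 from cells given an siRNA against NAMPT (siNAMPT). NAMPT makes nicotinamide mononucleotide from nicotinamide, the rate-limiting step of NAD salvage. The comparison asks which transcripts change when NAMPT is depleted. Total counts per library were 21556890, 21450910 and 21677176 for siControl and 22362310, 19510796 and 22364717 for siNAMPT. The first principal component held 60.5% of the variance and separated the groups, and the common biological coefficient of variation was 13%. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

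NAMPT fell in every siNAMPT library. Levels are given as CPM, read counts scaled to the size of each library by TMM. Its level was 173 ± 10.4 CPM (SD, n = 3) in siControl and 28.5 ± 1.53 CPM (SD, n = 3) in siNAMPT, which is 83.5% lower. The log2 fold change was −2.60 (SE 0.07), with adjusted p = 2.60e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The NAMPT counts were 3480, 3603 and 3996 in the siControl libraries and 594, 572 and 673 in the siNAMPT libraries. NAMPT (ENSG00000105835) lies on chromosome 7 from 106248285 to 106286326 in GRCh38 coordinates. An exact two-sided permutation test of the 3 values against 3 gave p = 0.1, the smallest p this design allows. The pseudogene NAMPTP1 fell too (log2 fold change −3.03), and reads of the gene and its near-identical copy could have been shared between them in counting.

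**Figure D1:**
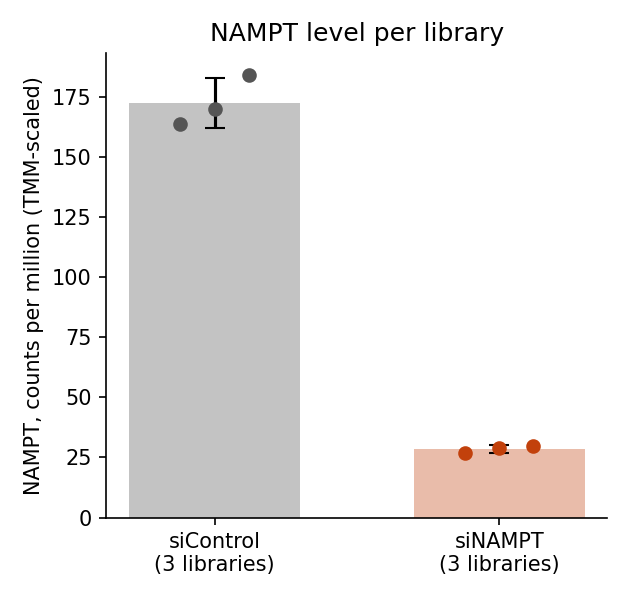
NAMPT in CPM (vertical axis, TMM-scaled) in each library, with bars for the group mean and error bars for the SD over 3 libraries. The siNAMPT libraries lie between 26.7 and 29.7 CPM, and the siControl libraries between 164 and 184 CPM.

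HMOX1, the heme oxygenase that degrades heme, had the largest rise of the genes named by rule, from 6.96 ± 0.260 CPM to 241 ± 17.5 CPM (SD, n = 3 each), a 34.6-fold difference (log2 fold change 5.11, SE 0.08, adjusted p = 3.46e-07). TNFSF10, the death ligand TRAIL, rose from 53.6 to 249 CPM, and TXNIP, an inhibitor of thioredoxin and of glucose uptake, from 85.0 to 316 CPM. FBXO32, a ubiquitin ligase subunit induced in atrophying muscle, rose 3.71-fold, and SAT1, which acetylates spermidine and spermine, rose 3.44-fold. KRT15, a keratin of basal epithelial cells, rose from 266 ± 5.11 to 958 ± 52.7 CPM (SD, n = 3 each). The other large rises were those of CYRIA (4.84-fold), TMPRSS11E (3.92-fold), NECTIN4 (3.91-fold), NANOS1 (3.88-fold), HABP4 (3.81-fold) and GPNMB (3.39-fold). All had adjusted p of 3.99e-05 or below in edgeR's quasi-likelihood test.

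The rule for named genes asks for a mean FPKM of at least 5 in the higher group. Within it the largest falls after NAMPTP1 were those of ANKRD1, LYPLA1P3, NAMPT itself, UHMK1, PTP4A1, LRRC58, CCL5, LYPLA1, IL7R, KCTD12 and GNG5. ANKRD1, a transcript induced by YAP and TAZ, was at 54.2 ± 1.48 CPM in siControl and 7.02 ± 1.06 CPM in siNAMPT (SD, n = 3 each), with log2 fold change −2.95 (SE 0.11) and adjusted p = 9.04e-06. The kinase UHMK1 (−2.57), the phosphatase PTP4A1 (−2.49), LRRC58 (−2.47), the depalmitoylating enzyme LYPLA1 (−2.38) and KCTD12 (−2.32) each carried at least 1 copy of the 7-base word TACCATA in the annotated 3′ UTR, a word described with its values further on. The chemokine CCL5 (−2.39) carried the shifted form ACCATAA. The interleukin receptor IL7R (−2.35) carried the shared 6-base core ACCATA, while ANKRD1 and GNG5 (−2.31) had none of these forms. LYPLA1P3 (−2.77) is a pseudogene of LYPLA1, and reads of the pair could have been shared in counting. In the paragraphs on gene lists only TACCATA and ACCATAA are marked, so an unmarked gene may still hold the core. The lower genes LIG4, NT5E, BIRC3, ETV5, CXCL6, GADD45A, ATG3 and TXNRD1 hold it as ACCATAT. Of genes that rose, EDEM1 holds it as ACCATAT and CLU as AACCATA.

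Of 15213 genes tested, 6500 changed, 3161 of them higher and 3339 lower in siNAMPT. At least 2-fold changes numbered 683 up and 576 down. The siNAMPT libraries all lay on one side of the siControl libraries for 54.9% of genes, where chance gives 10% for 3 against 3. The count of at least 2-fold changes, 1259 in all, was 282 of 11234 tested with limma on log2(FPKM + 1), where scale, test and filter differ together.

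**Figure D2:**
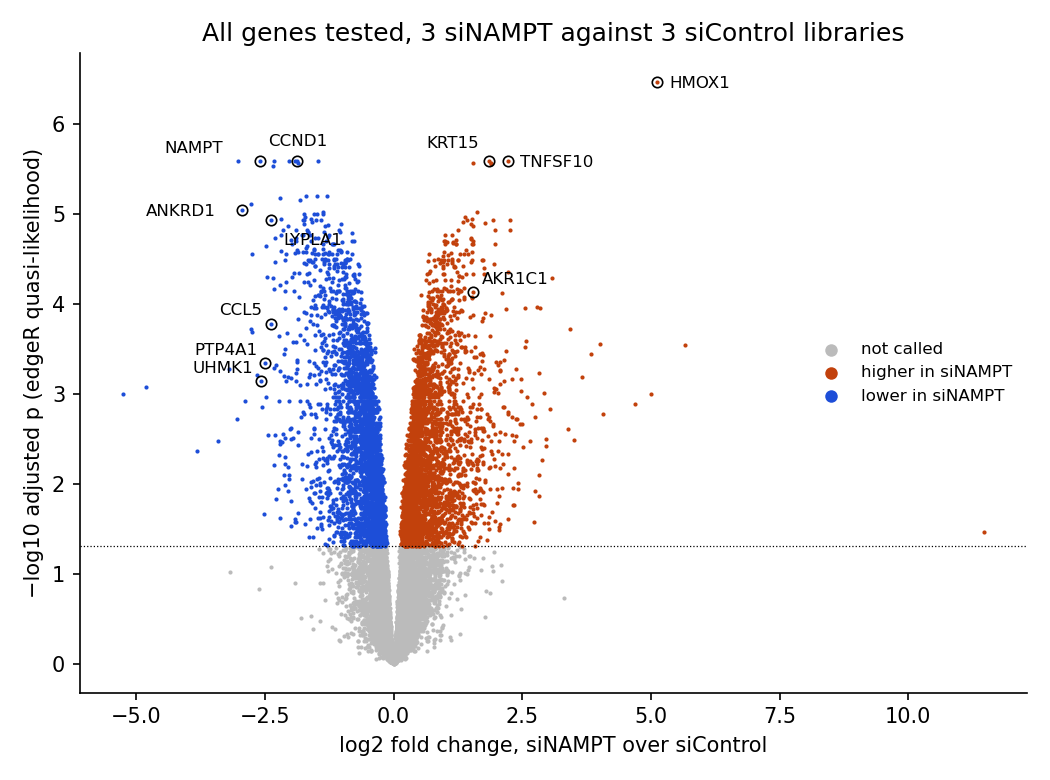
Log2 fold change of siNAMPT over siControl (horizontal axis) against −log10 of the adjusted p from edgeR's quasi-likelihood test (vertical axis) for all 15213 genes tested, with circles around named genes. HMOX1 stands apart at log2 5.11, and NAMPT lies at −2.60.

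The rest of the NAD salvage and synthesis genes did not follow NAMPT in a single direction. Of the 19 members tested other than NAMPT, 5 rose, 3 fell and 11 were not called, and the numbers adjusted over the list alone were again 5 and 3. NMRK1, the kinase that makes nicotinamide mononucleotide from nicotinamide riboside, rose from 25.3 ± 2.23 to 45.8 ± 2.08 CPM (SD, n = 3 each), with log2 fold change 0.86 and adjusted p = 2.64e-04 in edgeR's test. NADSYN1, the NAD synthetase, rose by log2 0.35, the NADH hydrolase NUDT12 by 0.58 and the tryptophan-degrading IDO1 by 1.07, the last at only 1.59 and 3.36 CPM. NT5E, the ectoenzyme CD73, fell 3.14-fold (log2 −1.65, adjusted p = 3.34e-05), and NMNAT2 fell by 0.57 on the log2 scale. KYNU (0.42) and NNMT (−0.50) passed the threshold with all 6 libraries, but lost the call when certain libraries were left out. KYNU had adjusted p = 0.0660 without siControl replicate 2, 0.0549 without siControl replicate 3 and 0.0589 without siNAMPT replicate 3, and NNMT had 0.0601 without siNAMPT replicate 1 and 0.0632 without siNAMPT replicate 3. KYNU also carried the word TACCATA in its 3′ UTR. The values of NAPRT (−0.23, adjusted p = 0.1636) and NMNAT1 (0.02, adjusted p = 0.8598) did not pass, though NAPRT was called lower (adjusted p = 0.0286) with an offset for GC content and length chosen after the data were seen. The list of 20 with NAMPT was not called (camera adjusted p = 0.4134, downward), its median being 0.07 and its mean −0.09. Without NAMPT, a test also chosen after the data were seen, the direction turned upward (adjusted p = 0.6837), with a median of 0.09 and a mean of 0.04. Among 24 NAD-consuming enzymes 7 rose and 4 fell (adjusted over the list alone, 7 and 4; list adjusted p = 0.2358). PARP9 (0.79) and PARP4 (0.67) rose, and the deacetylase SIRT1 (−0.43) and PARP12 (−0.81) fell.

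The fixed gene lists were compared with all other genes by camera, with a preset inter-gene correlation of 0.01. Of 36 lists, 16 were called, 6 up and 10 down, and 2 of them were also called with an estimated correlation: DNA replication with the G1/S transition, and heat shock proteins. With the genes whose 3′ UTR holds the word ACCATA left out, a restriction chosen after the data were seen, both had adjusted p = 0.0855 with an estimated correlation and were still called with the preset one, with medians of −0.48 and −0.30 against −0.48 and −0.35 with all genes. The following counts of members are over all genes tested unless stated.

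Genes of DNA replication and the G1/S transition fell together. Of 48 members, 38 fell, none rose and 10 were not called, and 40 fell when adjusted over the list alone. The list's median log2 fold change was −0.48, with camera adjusted p = 9.68e-12 and adjusted p = 0.0449 with an estimated correlation. DTL, which marks CDT1 for destruction in S phase, fell from 79.4 to 26.7 CPM, and cyclin E2 (CCNE2) from 18.9 to 6.78 CPM. Both hold TACCATA in the 3′ UTR. MCM7 and MCM2, subunits of the replicative helicase picked here after their values were seen, changed by −0.65 and −0.51. Among DNA repair genes 20 of 38 fell and 1 rose, against 21 and 2 adjusted over the list alone (camera adjusted p = 0.0028; adjusted p = 0.2304 with an estimated correlation). The ligases LIG3 (−1.28, with TACCATA in its 3′ UTR) and LIG4 (−1.14) fell most. Mitosis genes were not called as a list (adjusted p = 0.1467), with 19 of 50 lower and 4 higher (19 and 7 adjusted over the list alone), but were called lower with DESeq2 (adjusted p = 0.0245) and with no filter on low counts (0.0254). KIF23 (−0.83) and CDC20 (−0.64) fell, and NEK2 (0.52) and NUSAP1 (0.29) rose. Cyclin D1 (CCND1), in the list of senescence cell-cycle regulators, fell from 930 ± 11.3 to 254 ± 10.4 CPM (SD, n = 3 each) and carries ACCATAA in its 3′ UTR. In that list 3 of 19 members rose and 7 fell (4 and 8 adjusted over the list alone). The list had camera adjusted p = 0.1467, and 0.0271 with DESeq2. CDKN2B rose 2.67-fold, and TERT fell 2.29-fold, from only 2.45 to 1.06 CPM.

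Heat shock proteins were lower, with 13 of 21 down and 1 up (15 and 1 adjusted over the list alone), a median of −0.35, camera adjusted p = 1.22e-08 and adjusted p = 0.0449 with an estimated correlation. The HSP90 cochaperone CHORDC1 fell 4.13-fold and carries ACCATAA in its 3′ UTR. HSPH1 fell 2.76-fold with neither 7-base form. The small heat shock protein HSPB8 rose by 0.68. Genes of the integrated stress response fell as well, 22 of 38 against 2 that rose (22 and 2 adjusted over the list alone; camera adjusted p = 8.10e-05; adjusted p = 0.1901 with an estimated correlation). The glutathione-degrading enzyme CHAC1 (−2.20) and VLDLR (−2.47, from 1.14 CPM) fell most, while DDIT4, an inhibitor of mTORC1, rose from 318 to 628 CPM. Endoplasmic reticulum chaperones were not called as a list (adjusted p = 0.2620; 3 up and 5 down of 26, and 3 and 5 adjusted over the list alone). The chaperone HSPA5 fell from 1112 ± 4.17 to 404 ± 11.2 CPM (SD, n = 3 each), and its 3′ UTR holds TACCATA, as does that of the sensor ERN1 (−0.91). ERO1A (0.60) and EDEM1 (0.37) rose.

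Targets of NF-kB and secreted inflammatory factors were lower. Of 29 NF-kB targets 17 fell and 2 rose, the same numbers adjusted over the list alone, with a median of −0.74, camera adjusted p = 2.37e-06 and adjusted p = 0.0519 with an estimated correlation. BIRC3, an inhibitor of apoptosis, fell from 35.1 to 8.2 CPM, and CSF2 from 1.79 to 0.358 CPM, while IRF1 rose by 0.58. Of 33 senescence-associated secretory factors 16 fell and 4 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.0140; adjusted p = 0.1796 with an estimated correlation and 0.1028 with FPKM). In that list CXCL6 fell 3.67-fold, and MMP13 rose 2.12-fold. Immediate early genes fell in 15 and rose in 6 of 31 cases, or 17 and 7 adjusted over the list alone (camera adjusted p = 0.0020; adjusted p = 0.1275 with an estimated correlation and 0.0689 without genes holding ACCATA). ETV5 (−2.20) and SPRY4 (−1.99, from only 2.6 to 0.66 CPM), both induced by ERK signalling, fell, and BTG2 (1.51) and FOSB (0.99) rose. Interferon-stimulated genes went both ways, 14 up and 15 down of 42 (15 and 16 adjusted over the list alone; list adjusted p = 0.2467), with a median of 0.01 and a mean of −0.13. OAS3, which carries TACCATA, fell from 251 to 66.5 CPM and TRIM22 rose from 56.2 to 148 CPM.

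Genes of the NRF2 antioxidant response rose, 16 of 34 against 4 that fell, also when adjusted over the list alone (median 0.28, camera adjusted p = 1.37e-08; adjusted p = 0.1129 with an estimated correlation). Besides HMOX1, the aldo-keto reductase AKR1C1 rose 2.93-fold, though it carries ACCATAA in its 3′ UTR and reads could have been shared with near-identical paralogs. TXNRD1 (−0.67) and SRXN1 (−0.28), both known NRF2 targets, fell. In the ferroptosis list 6 of 23 rose and 6 fell, with the same numbers adjusted over the list alone (median 0.11, mean 0.23; camera adjusted p = 0.01, upward; adjusted p = 0.1496 with an estimated correlation). HMOX1 and SAT1 rose, and CHAC1 and DHODH (−0.86, with ACCATAA) fell. That call was lost without siNAMPT replicate 1 (adjusted p = 0.1108), with FPKM (0.2592) and with the offset (0.3371). It was also lost without HMOX1 (adjusted p = 0.3875, mean 0.00), a test chosen after the data were seen, while the NRF2 list was still called without it (3.18e-05, mean 0.35). Antioxidant enzymes were not called (adjusted p = 0.6832; 7 up and 4 down of 24, and 7 and 4 adjusted over the list alone). PRDX4 (0.93) rose and PRDX6 (−0.44) fell.

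Glycolysis genes were lower in 17 of 24 cases and higher in 2, with the same numbers adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.2033 with an estimated correlation). LDHA, lactate dehydrogenase A, fell from 2164 ± 272 to 817 ± 140 CPM (SD, n = 3 each) and ALDOC 2.38-fold. Both carry TACCATA. PFKL (0.48) and PFKFB2 (0.50, also with TACCATA) rose. In the pentose phosphate and serine pathways 6 of 20 rose and 8 fell (6 and 8 adjusted over the list alone), with a median of 0.05, a mean of −0.21 and a camera adjusted p of 0.0460 in the downward direction (adjusted p = 0.2463 with an estimated correlation). PRPS1 (−2.20) and PSAT1 (−1.81) fell and both carry TACCATA. The transketolase TKT rose from 644 to 1133 CPM. Hypoxia targets fell in 15 and rose in 5 of 30 cases, or 17 and 5 adjusted over the list alone (camera adjusted p = 0.0463; adjusted p = 0.3791 with an estimated correlation). BNIP3 fell 3.74-fold and BHLHE40 rose 2.18-fold. The pentose phosphate and serine call was lost without siControl replicates 1 or 2 (adjusted p = 0.0571 and 0.0629) or siNAMPT replicates 1, 2 or 3 (0.0733, 0.1159 and 0.0658), with FPKM (0.6048) and with the offset (0.3907), and the list turned upward without genes holding ACCATA (0.4835). The hypoxia call was lost without siControl replicate 1 (0.0560) or siNAMPT replicates 1 or 3 (0.0822 and 0.1007), with FPKM (0.5238), with the offset (0.0705) and without genes holding ACCATA (0.0769).

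Cholesterol genes rose in 15 and fell in 2 of 28 cases, or 16 and 2 adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.2304 with an estimated correlation). HMGCS1, which makes HMG-CoA, rose from 166 to 333 CPM. SQLE, which carries TACCATA, fell 2.35-fold, and MYLIP fell by 0.54 on the log2 scale. Genes of fatty acid synthesis and oxidation rose in 12 and fell in 3 of 33 cases, the same numbers adjusted over the list alone (camera adjusted p = 0.0069; adjusted p = 0.1275 with an estimated correlation). ACSL1, an acyl-CoA synthetase, rose 2.90-fold and HADHB 1.73-fold, while FADS1 (−0.35) and ELOVL5 (−0.27) fell. Replication-dependent histone genes rose in 12 and fell in 3 of 26 cases, again the same adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.1275 with an estimated correlation). H2BC5 rose 3.33-fold and H2BC12 fell 1.64-fold, and copies of histone genes can share reads.

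Mitochondrial and degradation lists were not called with edgeR, but all 5 were with DESeq2, where the gene statistic and the list test both differ. Transcripts of the mitochondrial genome rose in 8 and fell in 1 of 13 cases, or 10 and 1 adjusted over the list alone (list adjusted p = 0.1467), with MT-ND5 and MT-CO1 each up by 0.25. Mitochondrial transcripts took 5.68 to 6.03% of the counts in siControl and 6.89 to 7.04% in siNAMPT. Nuclear genes of oxidative phosphorylation rose in 5 and fell in 15 of 63 cases, or 5 and 14 adjusted over the list alone (adjusted p = 0.1682). COX7C fell by 1.69 on the log2 scale, NDUFB6, with TACCATA, by 1.29, and NDUFC1 (0.40) rose. Tricarboxylic acid cycle genes rose in 4 and fell in 12 of 30 cases, or 6 and 14 adjusted over the list alone (adjusted p = 0.1467), with IDH2 down 4.24-fold and SUCLG2 up 1.42-fold. Genes of mitochondrial dynamics, mitophagy and biogenesis rose in 5 and fell in 13 of 29 cases, as they did adjusted over the list alone (adjusted p = 0.0925), MFN1 (0.63) rising and ESRRA (−1.07) falling. Autophagy and lysosome genes rose in 15 and fell in 5 of 41 cases, or 16 and 5 adjusted over the list alone (adjusted p = 0.0982), with ULK1 up 2.59-fold, GABARAPL1 up 3.37-fold and ATG3 down 2.24-fold. With DESeq2 the mitochondrial genome (adjusted p = 0.0385) and autophagy (0.0221) were called higher, and oxidative phosphorylation (0.0303), the tricarboxylic acid cycle (0.0222) and mitochondrial dynamics (0.0205) lower. The directions were the same with no filter, where oxidative phosphorylation (0.0327), the tricarboxylic acid cycle (0.0310), mitochondrial dynamics (0.0204) and autophagy (0.0499) were called, with FPKM for the mitochondrial genome (0.0218) and autophagy (0.0117), and with the offset for oxidative phosphorylation (0.0093) and the tricarboxylic acid cycle (0.0364).

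Lists of cell death and of damage signalling were mixed. Of 28 p53 targets 10 rose and 9 fell, or 11 and 9 adjusted over the list alone (adjusted p = 0.6832). TP53INP1 rose 3.33-fold, GADD45A fell 2.57-fold, and FAS, with TACCATA in its 3′ UTR, fell 3.81-fold. Apoptosis regulators rose in 11 and fell in 10 of 34 cases, also when adjusted over the list alone (adjusted p = 0.7104), with BMF (1.40) up and BIRC3 (−2.10) and FAS (−1.93) down. The list had a median of −0.05, a mean of 0.05 and an upward direction of the test. The list set up for nuclear-retained RNAs, kept as a sign of RNA quality, rose in 4 and fell in 2 of 17 cases (4 and 2 adjusted over the list alone; adjusted p = 0.1888). It also holds NORAD, an RNA found mainly in the cytoplasm, which rose by 0.61, so the list does not measure nuclear RNA alone. Of 13 genes of the RNA interference machinery 2 rose and 6 fell (2 and 6 adjusted over the list alone; adjusted p = 0.3334), among them AGO2 (−0.55) and AGO4 (0.82).

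**Figure D3:**
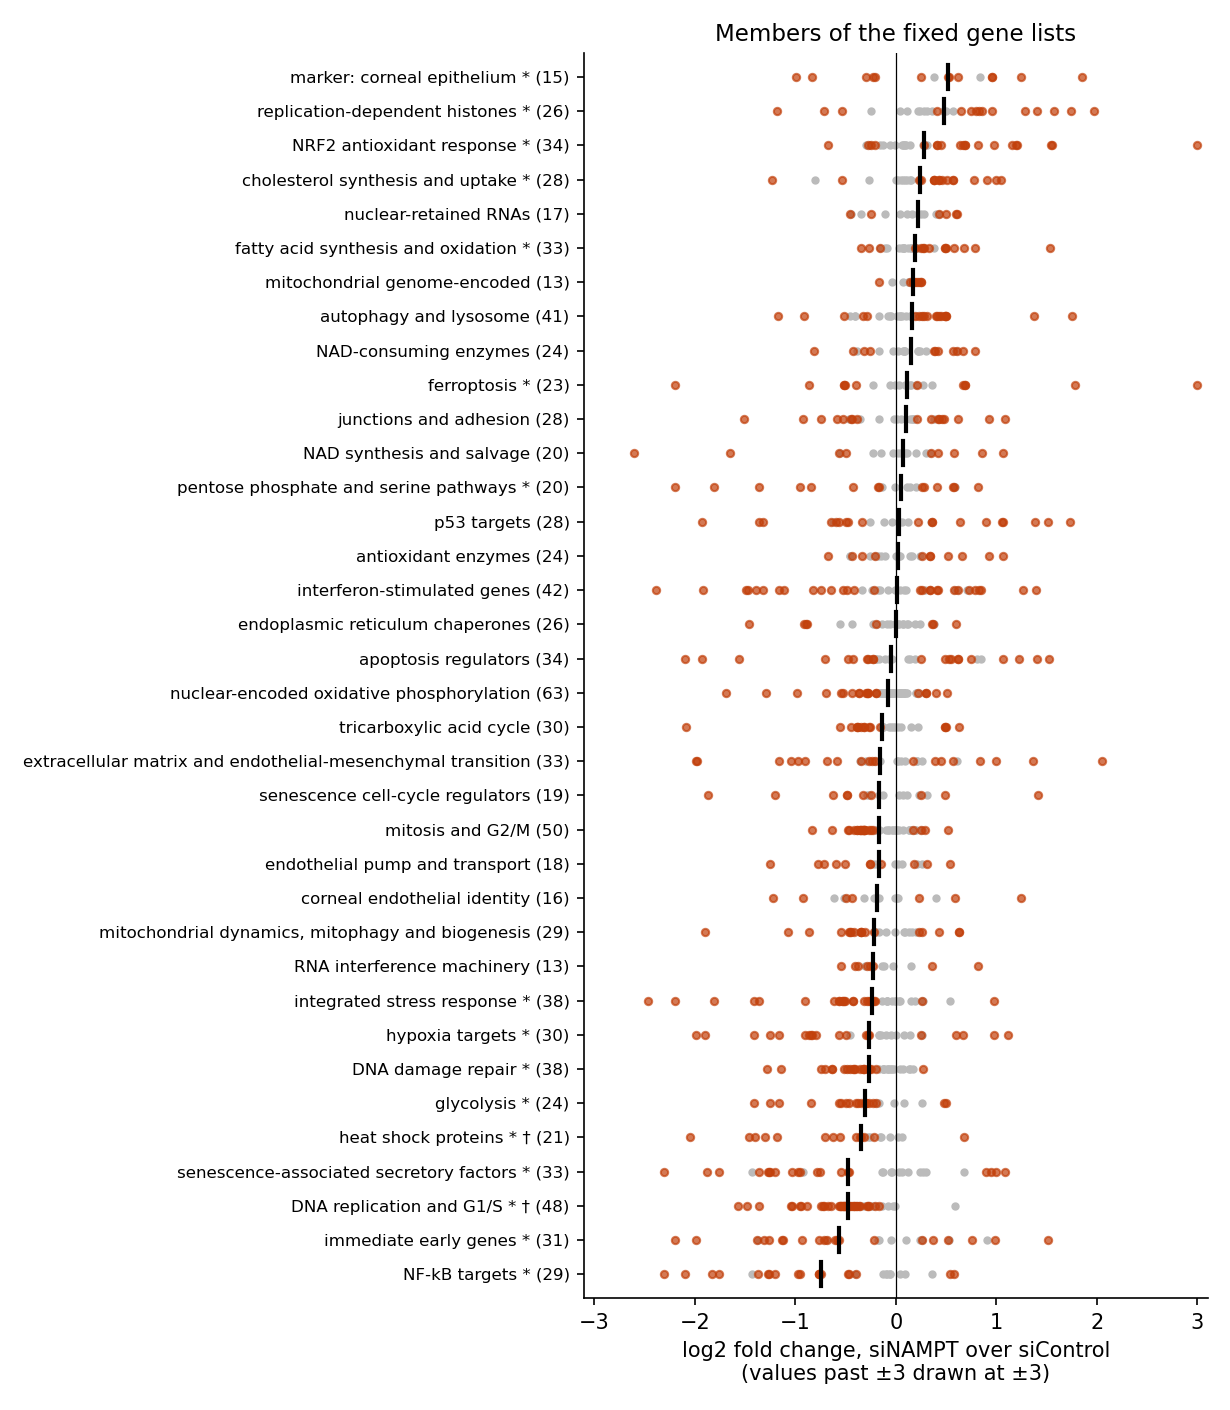
Log2 fold change of siNAMPT over siControl (horizontal axis) for each tested member of the 36 lists, 1 list per line with the number of members in brackets. Orange points passed the gene threshold and grey points did not, the black bar is the list median, a star marks lists called with the preset correlation and a dagger the 2 lists also called with an estimated correlation. The medians run from −0.74 for NF-kB targets to 0.52 for corneal epithelium markers.

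Genes of corneal endothelial identity and pump function were not called as lists. Of 27 identity genes 16 could be tested, 3 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.4197). N-cadherin (CDH2) fell from 169 to 89.0 CPM and the transcription factor FOXC1 rose from 36.6 to 55.2 CPM. Among 18 pump and transport genes 3 rose and 8 fell, or 4 and 8 adjusted over the list alone (adjusted p = 0.3066), with carbonic anhydrase CA2 up 1.45-fold and ATP1B3 up 1.24-fold. Junction and adhesion genes rose in 9 and fell in 8 of 28 cases, or 9 and 9 adjusted over the list alone (camera adjusted p = 0.6832, median 0.10, mean −0.02). F11R rose 2.14-fold, and GJB2 fell 2.85-fold, from only 1.61 to 0.564 CPM. Genes of the extracellular matrix and endothelial-mesenchymal transition rose in 8 and fell in 13 of 33 cases, or 9 and 15 adjusted over the list alone (adjusted p = 0.3066). TGFB2, with TACCATA, fell from 36.4 to 9.23 CPM and clusterin (CLU) rose from 40.2 to 103 CPM.

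Of the 17 markers in the corneal epithelium list, 14 reached 1 FPKM in a group, and many differed between the groups. Of 15 tested 8 rose and 5 fell, or 9 and 5 adjusted over the list alone (median 0.52, camera adjusted p = 0.0020; adjusted p = 0.2304 with an estimated correlation, 0.1232 with FPKM and 0.1195 with the offset). Besides KRT15, the transcription factor ELF3 rose 2.37-fold, while the desmosomal cadherin DSG3, with ACCATAA in its 3′ UTR, fell 1.99-fold. In siControl KRT14 was at 544 ± 33.4 FPKM and KRT5 at 236 ± 11.9 FPKM (SD, n = 3 each), and averaged over all libraries they lay above 99.8% and 99.6% of the genes with a count. KRT6A stood at 114, S100A14 at 94.1 and TP63, the basal epithelial transcription factor, at 5.38 FPKM. KRT12 had no count in any library, and PAX6 had at most 5. KRT3 was at 0.313 FPKM in siControl and 0.571 FPKM in siNAMPT. With these members so low, the abundant ones do not by themselves show corneal epithelium. The median over the 17 markers was 17.9 FPKM in siControl and 28.3 FPKM in siNAMPT. The 27 corneal endothelial identity genes had a median of 0.0714 FPKM in siControl and 0.0746 FPKM in siNAMPT, and 8 of them reached 1 FPKM in a group. COL8A1 was at 0.0714 and COL8A2 at 0.0151 FPKM in siControl, and TFAP2B had no count in any library. CDH2 (26.2 FPKM), FOXC1 (9.25) and SLC4A11 (5.32) were present in siControl. The intermediate filament gene VIM, a gene added after its value was seen, was at 0.285 ± 0.0530 FPKM in siControl and 0.333 ± 0.0339 FPKM in siNAMPT (SD, n = 3 each). Markers of corneal stroma, vascular endothelium, leukocytes and melanocytes or neural crest had fewer than 5 testable members each. Their list medians in siControl were 0.00887, 0.00702, 0.00593 and 0.00252 FPKM, and their highest members in siControl were ALDH3A1 (22.8 FPKM), EGFL7 (1.32), CD68 (1.91) and ERBB3 (2.26).

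**Figure D4:**
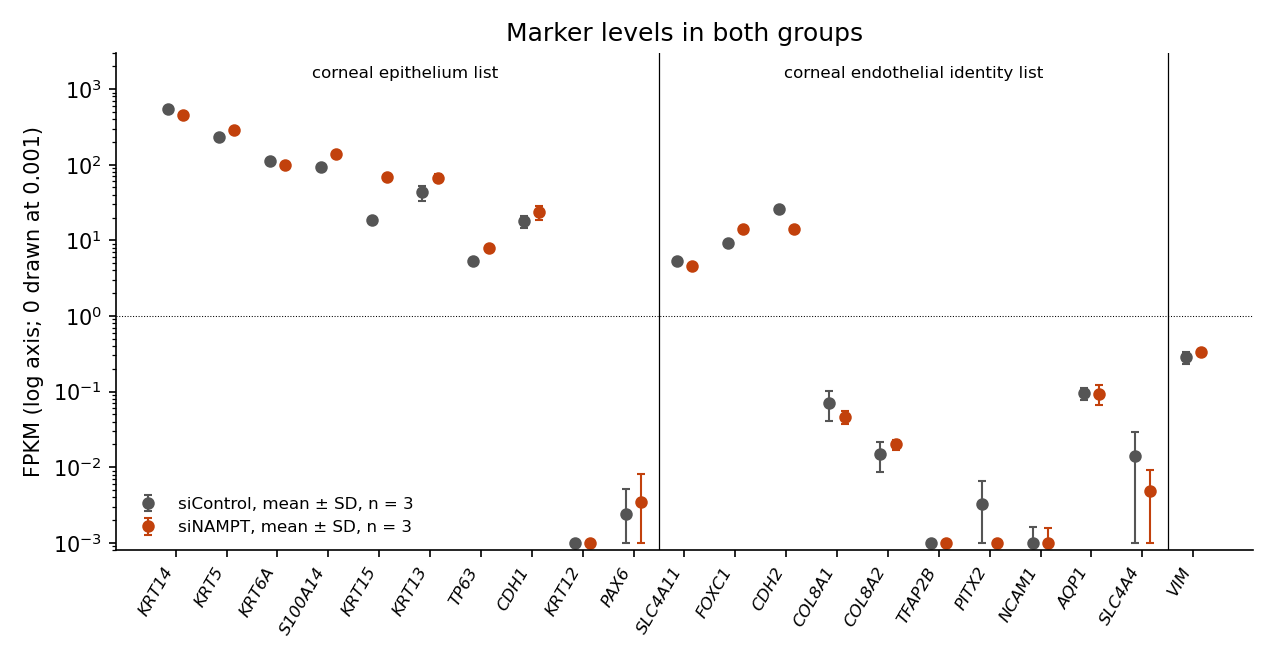
FPKM on a log axis (vertical) of selected members of the corneal epithelium and corneal endothelial identity lists and of VIM, as mean and SD over 3 libraries per group, with 0 drawn at the bottom. KRT14 reaches 544 FPKM in siControl, and COL8A1, COL8A2 and VIM lie below 1 FPKM in both groups.

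Transcripts with a particular short word in the 3′ UTR were lower in siNAMPT. All 7-base words present in at least 100 of 11498 protein-coding genes were compared by a regression of log2 fold change on the presence of the word, with UTR length, base composition and mean expression as covariates. The word with the lowest t was TACCATA (t = −20.42), where 100 permutations reached −4.76 at the lowest. Its 901 carriers had a median log2 fold change of −0.32, and 49.6% of them were called lower, against −0.01 and 23.6% for the other genes. In all, 33 words lay below the permutations, among them TATTTAT (t = −7.36), which lacks the core ACCATA. A t outside the permutations alone therefore does not point to the siRNA. By longest match, the median was −0.47 for 285 genes with TACCATAA, −0.28 for 616 with TACCATA only, −0.19 for 559 with ACCATAA, −0.08 for 1144 with ACCATA and 0.01 for 8894 genes with none. These medians were not adjusted for UTR length, whose median fell in the same order (3318, 3126, 2780, 2632 and 837 bases). TACCATAA occurs once in the NAMPT coding sequence, on the minus strand of chromosome 7 from 106263610 to 106263617 (GRCh38), in exon 7 of the 11 exons of transcript NAMPT-201. Among the 12 largest falls named by rule, 6 of the 9 whose 3′ UTR was searched carried a 7-base form, and none of the 12 largest rises named by rule did. The words came from a scan over all sequences, not from the siRNA, whose sequence is not given in the sources used here.

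**Figure D5:**
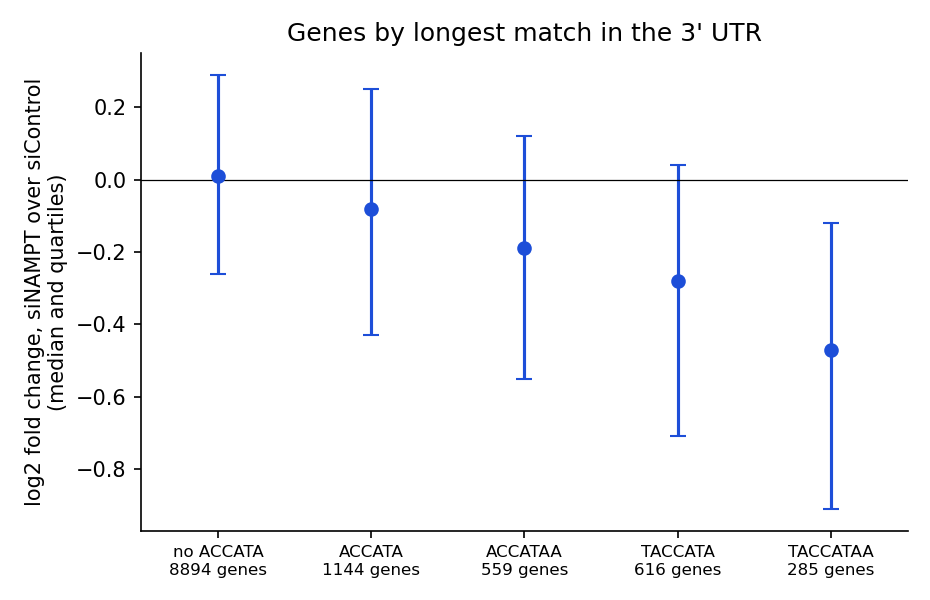
Median log2 fold change of siNAMPT over siControl, with lower and upper quartiles (vertical axis), for genes grouped by the longest match in the 3′ UTR (horizontal axis, with the number of genes). The median, not adjusted for UTR length, goes from 0.01 with no match to −0.47 with TACCATAA.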

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

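The offset for GC content and length, the restriction to genes without the word ACCATA, the NAD synthesis list without NAMPT and the lists without HMOX1 were tests chosen after seeing the data. The others were set before the data were examined. NAMPT fell under every alternative run, with log2 fold changes from −2.61 to −2.19, and from −2.64 to −2.55 when 1 library was left out. The count of genes changed was 5435 to 7254 over DESeq2, RLE, no filter, FPKM, the replicate block and the offset, and 5145 to 5886 without 1 library. Among genes whose 3′ UTR was searched and lacks ACCATA the counts were 3988 changed, 2034 higher, 1954 lower and 457 changed at least 2-fold of 8894 tested, where both the smaller number of genes and the loss of the word's carriers lower the counts. With limma on log2(FPKM + 1) the count of at least 2-fold changes was 282, and without 1 library it was 1218 to 1258. No gene called in both went the other way under any alternative. Of the 152 named genes called, 140 to 146 kept call and direction without 1 library, and 132 to 152 otherwise, where genes missing from the FPKM filter count as lost. The number of lists called was 13 to 16 without 1 library, 23 with DESeq2 and 2 with an estimated correlation. With FPKM the calls were lost for secretory factors (adjusted p = 0.1028), ferroptosis (0.2592), hypoxia (0.5238), pentose phosphate and serine pathways (0.6048) and corneal epithelium markers (0.1232). With the offset they were lost for ferroptosis (0.3371), hypoxia (0.0705), pentose phosphate and serine pathways (0.3907) and corneal epithelium markers (0.1195). Without HMOX1 the ferroptosis call was lost (0.3875).

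Of values not past the threshold, the direction turned for TDO2 (0.11 with the offset, and −0.21 to 0.13 without 1 library) and NMNAT1 (−0.01 with the offset, and −0.03 to 0.06 without 1 library). It also turned for the lists NAD synthesis (upward, adjusted p = 0.7767 with FPKM, 0.7652 with the offset, 0.4144 without the word and 0.6837 without NAMPT), apoptosis regulators (0.9436 with FPKM) and antioxidant enzymes (0.7652 with the offset). Without genes holding the word it turned for interferon-stimulated genes (0.4822). The pentose phosphate and serine list, called lower with all genes, turned upward without those genes (0.4835). The cause was not tested. Of NAD genes not called, NNT was called higher without siNAMPT replicate 1 (adjusted p = 0.0186) and with the offset (0.0052), SLC25A51 higher without siNAMPT replicate 1 (0.0395) and NAPRT lower with the offset (0.0286).

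The replicate numbers gave no clear sign of paired samples, though 3 libraries per group are too few to exclude pairing. Deviations from the group means correlated at 0.13, −0.07 and 0.10 between libraries of the same number, and 3 of 6 libraries correlated best with their own number. With the replicate block 6336 genes changed and 15 lists were called, with autophagy and lysosome (adjusted p = 0.0496) among them and without ferroptosis (0.2072) or the pentose phosphate and serine pathways (0.2958). NNT was called higher (0.0432).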

Other observations

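Several tests were chosen after the results were seen. They are those of direct pairing with the word as the whole cause, of the control siRNA's word, of the lists without carriers of the word, of the cell profile and of BACH1. The others were written down before their results. The tests written down before include that of gene length and GC content. Its offset was not among the alternatives fixed before the data were examined, and is called chosen afterwards where it serves as an alternative.

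Counts of the UGT1A family, whose members share exons, differed widely between replicates. UGT1A10 had no count in the siControl libraries and 1013, 33 and 58 counts in the siNAMPT libraries, so its fitted change is not used. Ribosomal RNA of mitochondria (MT-RNR1 and MT-RNR2) took 0.74 to 0.77% of the counts in siControl and 1.05 to 1.16% in siNAMPT. Of the 12 genes named by rule for the largest rise, TNFSF10 and NANOS1 hold the 6-base core ACCATA and the other 10 do not.

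The split of the 6 libraries by siRNA called 6500 genes and the highest of the other 9 splits called 1. For gene lists it called 16 with the preset correlation, and the highest of the other splits called 13. In each case only 1 of the 10 splits reached the real value, and 10 splits are too few to exclude chance at 0.05. The other splits also put libraries of both siRNAs in both of their groups. The siRNA difference then widens the spread within groups, which lowers the gene calls, and part of it stays between groups. Their counts of genes and lists therefore do not measure chance.

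The first pattern is the lower level of transcripts with TACCATA. The value t = −20.42, from a fit with UTR length as a covariate, is what repression through a seed of the siRNA could produce. The sequence of the siRNA is not given in the sources used here. Changes were also graded by length of match, but those medians were not adjusted for UTR length, which fell in the same order. The word's presence in 2 of 4 NAMPT transcripts adds little, since 26.3% of the words tested occur in NAMPT. Direct pairing of a seed with the core ACCATA in each gene's own searched 3′ UTR is argued against as the whole cause for the genes called lower as a set. Effects that pass through carriers of the word, and sites outside the searched UTRs, are not covered by this test. Of those searched, 35.6% hold the 6-base core, against 18.2% of the others, shares not adjusted for UTR length. The share is 56.9% among those lower by at least 2-fold, where 182 of 427 hold a 7-base form. A trend with gene length and GC content is argued against as well, since 97.1% of the genes called lower kept the call after the offset. What stays open is the source of the changes in genes without the word. They may follow from NAMPT loss or from the fall of genes with TACCATA or ACCATAA, such as CCND1, HSPA5, LDHA and BACH1. Whether the word lowered each of these genes was not tested. A second siRNA or a rescue with NAMPT or NAD was not analysed here.

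With the analysis restricted to genes without ACCATA, DNA replication and G1/S (34 of 43 lower, adjusted p = 1.10e-10), heat shock proteins (10 of 18 lower, adjusted p = 4.40e-05) and the NRF2 list (13 of 30 higher, adjusted p = 1.28e-06) were among 13 of the 16 lists called again in the same direction with the preset correlation. Their medians were −0.48, −0.30 and 0.20, against −0.48, −0.35 and 0.28 with all genes. With an estimated correlation their adjusted p were 0.0855, 0.0855 and 0.1132, against 0.0449, 0.0449 and 0.1129. Immediate early genes (adjusted p = 0.0689), hypoxia targets (adjusted p = 0.0769) and the pentose phosphate and serine pathways (adjusted p = 0.4835, now upward) were no longer called. TCGGAGA went with higher values in siNAMPT (t = 7.09, where permutations reached 5.38), as a seed of the control siRNA could produce. A t outside the permutations alone does not show such a seed, since TATTTAT, without the core ACCATA, also lay outside (t = −7.36).

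The second pattern is the epithelial profile. A small share of epithelial cells among corneal endothelial cells is argued against by a median of the corneal endothelial identity genes of at most 0.0922 FPKM in any library and by VIM at no more than 0.366 FPKM, with epithelial marker medians of 14.2 to 29.6 FPKM. Of the 13 markers above 10 CPM, 8 rose and 4 fell in siNAMPT. KRT14 fell by 0.30, KRT6A by 0.23, EPCAM by 0.21 and DSG3, which carries ACCATAA, by 0.99 on the log2 scale. These values argue against a larger share of epithelial cells in siNAMPT as the only source of the marker changes. A larger share together with changes within cells could also give falls, so it is not excluded. The profile may be that of the line as grown here or of other cells under its name, and no reference library of the line was analysed here, so this stays open.

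The third pattern is the rise of histone genes, whose median log2 fold change was 0.48 over 26 genes. Less strict selection of poly(A) RNA would raise other RNAs without a tail, and the 4 that could be tested (SNORD17, SNORA73B, SNORA71B and RN7SL2) had a median of −0.69 (bootstrap SD 0.13), below 0.24, the bound set before. SNORD17 fell (−1.01, adjusted p = 0.0060 in edgeR's test). These values argue against it for the 4 genes only, which lie at 0.466 to 5.0 CPM. Just SNORD17 among them was called, and no least number of genes was set before. The share of counts from MT-RNR1 and MT-RNR2, not part of the test, went the other way. It was 0.74 to 0.77% in siControl and 1.05 to 1.16% in siNAMPT, so less strict selection is not excluded. Reads shared between histone copies were not tested and stay open, as does a change in the transcripts.

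A hypothesis concerns HMOX1, which rose more than any other gene of the NRF2 list, the next being AKR1C1 (1.55). BACH1, the repressor of HMOX1, holds TACCATA at 2 places in its 3′ UTR and fell (log2 fold change −1.01, SE 0.17, adjusted p = 0.0030 in edgeR's test). Loss of BACH1 through the siRNA seed may therefore contribute to the rise of HMOX1, but NAMPT and BACH1 fell in the same 3 libraries, and these data cannot separate them. BACH1 expressed without its 3′ UTR, or an siRNA against NAMPT with another seed, would test it.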
